A study of Mus musculus with 4 samples.

How the data were processed

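LSK cells are the Lin-negative, Sca-1-high, c-Kit-positive fraction of bone marrow that holds haematopoietic stem cells and early progenitors. The series covers LSK cells of wild-type mice and of mice lacking Hdac6, an X-linked lysine deacetylase gene. Each genotype has 1 whole-genome bisulfite library (WGBS) and 1 oxidative bisulfite library (oxWGBS), so the 4 libraries form 4 groups of 1. Bisulfite sequencing reads 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC) alike as methylated. An oxidation step before bisulfite treatment leaves only 5mC to be read as methylated, so the difference of both measurements estimates 5hmC. Per the labels, the WGBS libraries are titled 5mC and numbered 1, and the oxWGBS libraries are titled 5hmC and numbered 2. Whether both libraries of a genotype came from the same animal, and which libraries gave each deposited level, is not given in the sources used here. The labels do not give the sex or strain of the animals.

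Per the labels' protocols, DNA was mixed with lambda control DNA, sonicated, ligated to methylated adapters, converted with a commercial bisulfite kit, amplified and sequenced on an Illumina instrument. The aligner, the methylation caller, the statistical test, the coverage filter and the conversion rate are not given in the sources used here. The deposited workbook holds 2 tables of the authors' own comparison, knockout against wild type, for 5mC and 5hmC. Although the study's design speaks of regions, each entry of both tables is a single cytosine position. Per the file headers, each position has a wild-type level, a knockout level, their difference, a p-value and a q-value. The deposited levels are fractions from 0 to 1, computed by the authors from read counts that are not analysed here; they are printed below as percent. The deposited p-values and q-values are the authors' own and compare 1 library with 1 library of the other genotype, not the genotypes as populations. The authors' differences equalled the knockout level minus the wild-type level within 0.0001. All deposited p-values lay under 0.01, and the smallest absolute difference was 10 percentage points in both tables. Coverage is not stated, so no interval for a single level can be given, and no read counts were inferred from the fractions. No spread between animals can be estimated for any value, and no p-value of the present work was computed.

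The submitters' processing notes name the mouse build GRCm39. The available gene table is of GRCm38, so the build of the positions was tested. Wild-type 5mC at listed sites within 500 bp of a gene end averaged 55.4% when gene positions of GRCm38 were used as they stand. Over 101 shifts of the gene positions, from 500 kb down to 500 kb up in steps of 10 kb, the lowest other average was 68.0%. In the last 30 Mb of each autosome, where builds would have drifted apart furthest, the averages were 56.1% unshifted and 66.0% at the lowest other shift. Taken by chromosome, the average was lowest unshifted on 14 of 19 autosomes and at another shift on the rest. Over all autosomes the dip at gene ends stands at the GRCm38 positions, and all positions below are given as GRCm38.

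Sites were assigned to 34614 genes, of which 21887 were protein-coding and 12727 long non-coding. A site belonged to a gene if it lay inside it or within 2000 bp of either end. The gene table gives neither strand nor exons, so promoters, exons, introns and UTRs could not be separated; "gene end" below means within 2000 bp of either end. A site in overlapping genes was assigned to each of them. Of 367 list entries, 366 were matched to the gene table. For each of 12 gene lists, the number of members with a listed site was set beside 10000 random lists of the same size, matched on biotype and on gene length in 20 bins; the percentile describes these tables and is not a test of genotypes. The numbers of cytosines tested were recovered from the deposited p-values and q-values, since a Benjamini-Hochberg q is p times the number of tests divided by rank. This gave 16859670 tests for 5mC and 16223319 for 5hmC. Within a tolerance of 0.001, 94.0% of 368 and 96.2% of 2711 q-values gave whole ranks. Positions of the cytosines that were tested but not listed were not used here, so no enrichment over the genome can be given. The number of shared positions expected by chance was the product of both list lengths divided by 16859670, which takes the tested cytosines of both tables as a common set and ignores differences in coverage; it replaced, after the data were seen, shuffles over whole chromosomes, which gave 3.51 on average over 1000 shuffles and also place sites at bases that were never tested. Directions were shuffled over single sites 1000 times for runs.

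The gene lists, the rule for naming genes, the location classes and most alternatives were fixed before the data were examined. The rule named, per table and direction, the 6 genes with the largest difference; 10 genes with opposite differences at gene ends; up to 4 members of each list by difference; and always Hdac6, Idh1, Idh2, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a and Dnmt3b. Some genes chosen by this rule are not reported here. Ties in the difference were broken by the smaller p-value, a choice made after the data were seen. Also chosen after the data were seen were the use of gene ends in place of promoters, the count of genes without positions listed in both tables, the counting of sites rather than members per list, with and without the gene with most sites, the recovered test numbers, the build test, runs of neighbouring sites, and the stretches of chromosomes X, 17, 2, 3 and 7. In counts of sites per list, sites in overlapping list members were counted once, which was also decided afterwards. In counts of members, such a site counted for each overlapping member. A run is at least 4 listed sites with gaps of at most 300 bp that all differ in the same direction; genes named for their runs or their small q were picked after their values were seen.

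Alternatives covered a larger minimum difference, the sites with the smaller p-values, autosomes alone, genes in place of sites, a q-value under 0.05, sites absent from the other table, narrower gene ends, and random lists not matched on length. Filters on the number of CpGs per region, and on coverage, and tests of read counts, could not be run, because the tables hold single positions without counts. Shares of covered bases and a minimum overlap of regions coincide with counts of positions for single bases. The authors' annotation columns were not used here, and the plan for regions was applied to sites. Shares of sites carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over listed sites only and treat neighbouring sites as independent. The count of sites per list, not the count of members, was tested on simulated data. There, 3 of 50 lists of 40 unchanged genes exceeded the 95th percentile, as did 50 of 50 lists given 3 times the sites. The simulated sites fell on genes independently and in proportion to length, so runs of sites and the count of members were not covered. The recovery of test numbers returned the true number in 2 of 2 simulations. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, with figures drawn in matplotlib 3.10.9.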

Results

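Cytosine methylation and hydroxymethylation were compared between wild-type and Hdac6-deficient LSK cells, the stem and progenitor fraction of mouse bone marrow. The study's design asks which sites gain or lose either mark without HDAC6, and its title ties the enzyme to IDH1. The isocitrate dehydrogenases make 2-oxoglutarate, the co-substrate of the TET enzymes that turn 5mC into 5hmC. Each genotype was represented by 1 bisulfite and 1 oxidative bisulfite library, so no difference below has a replicate check. The authors' deposited table for 5mC lists 53206 positions, and that for 5hmC lists 71864. Coverage is not stated, and positions are given on GRCm38. At Lsamp, 5hmC levels of 100% and 0% came with a p of 0.00794 in the authors' deposited table, which only a small number of reads would give. Levels of 0% and 100% named below can thus rest on few reads.

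Hdac6 itself carried 2 listed 5mC sites and 2 listed 5hmC sites, all lower in the knockout. At chromosome X position 7940288, inside the gene, the authors' deposited table gave 100% 5mC in wild type and 0% in the knockout (p = 0.000583, q = 1). The 5hmC level at position 7937031 was 63.2% in wild type and 0% in the knockout (p = 9.02e-06, q = 0.0642 in the authors' deposited table). Which part of the gene was deleted is not given in the sources used here, so these levels do not check the genotype.

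5mC was lower in the knockout at most listed sites, though not at most runs of neighbouring sites or at most sites with small q outside the Hdac6 and chromosome 17 stretches. The 6 named genes with the largest loss, each at 100% in wild type and 0% in the knockout in the authors' deposited table, were Rpgr, Fthl17f, H2al1o, Sytl5, Wdr13 and Gata1, and all of them lie close to Hdac6 on chromosome X. In all, 187 5mC sites tied at a difference of 100 points in either direction, and the smaller p-value decided which were named. The place of these 6 genes thus also reflects where p was small. Gata1 encodes the master transcription factor of erythroid and megakaryocytic cells; its site at position 7975531 had p = 1.08e-05 and q = 0.245 in the authors' deposited table. Rpgr, at position 10159503, had the smallest q of the named sites (p = 5.63e-19, q = 8.87e-14, the authors' deposited table). Cpn1, F11r, Rps6ka3, Socs7, Lpxn and Prss58 each held a site at 0% in wild type and 100% in the knockout, and the smallest q among these was 0.697, at Cpn1 in the authors' deposited table.

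Of the 53206 5mC sites, 31741 were lower and 21465 higher in the knockout, a share of 40.3% higher (95% interval 39.9 to 40.8%). The median difference was -23.26 percentage points over all listed sites, 34.0 points at the higher sites and -37.6 points at the lower ones. Near gene ends, 48.0% of the 8178 sites were higher, against 39.8% of the 21906 sites deeper inside genes and 38.1% of the 22902 sites between genes. As fractions, the median wild-type levels of these sites were 0.714, 0.853 and 0.875. Whether the wild-type level accounts for the different shares was not tested. In the authors' deposited table, q was under 0.05 at 93 sites (34 higher, 59 lower) and equal to 1 at 98.9% of sites. Of those 93 sites, 39 lay within 4 Mb of Hdac6 and all 39 were lower; 9 lay on chromosome 17 from 24 to 52 Mb and all 9 were higher. Without both stretches 45 sites remained, 25 higher and 20 lower, so the lower majority among the sites with small q rested on the Hdac6 stretch. Runs of neighbouring sites with a common direction were higher in 79 of 127 cases. A q of 1, reached at a p of about 7.15e-05, means that uniform p-values would give at least as many cytosines with so small a p among all those tested. With uniform p-values, 168597 of the tested cytosines would have p under 0.01, more than the 53206 listed. For 5hmC these numbers are 162233 and 71864. All listed sites also differ by at least 10 percentage points, so the numbers are not strictly alike. The authors' test is not given, and without a difference its p-values need not be uniform. These numbers are thus a reference and not a measured chance expectation. By q alone, most listed sites cannot be told from chance.

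Outside chromosome X, small q-values stood at few named genes. Ntrk3, a neurotrophin receptor gene, was at 15.9% in wild type and 93.6% in the knockout at chromosome 7 position 78178839 (q = 6.04e-10 in the authors' deposited table). Spg11, on chromosome 2 at position 122098051, was at 100% in wild type and 51.1% in the knockout (q = 6.51e-06, the authors' deposited table). This site lies in a stretch of chromosome 2 from 118 to 124 Mb where 282 of 316 sites were lower, so the difference is not particular to Spg11. It is among the sites counted above as outside the Hdac6 and chromosome 17 stretches. The smallest q of all 5mC sites, 1.22e-53, was at chromosome 2 position 98662629, outside any gene, where levels in the authors' deposited table were 26.3% and 37.6%. Read depth there is unknown, so this q need not mark a large difference. That site too is among those counted above as outside the Hdac6 and chromosome 17 stretches.

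**Figure D1:**
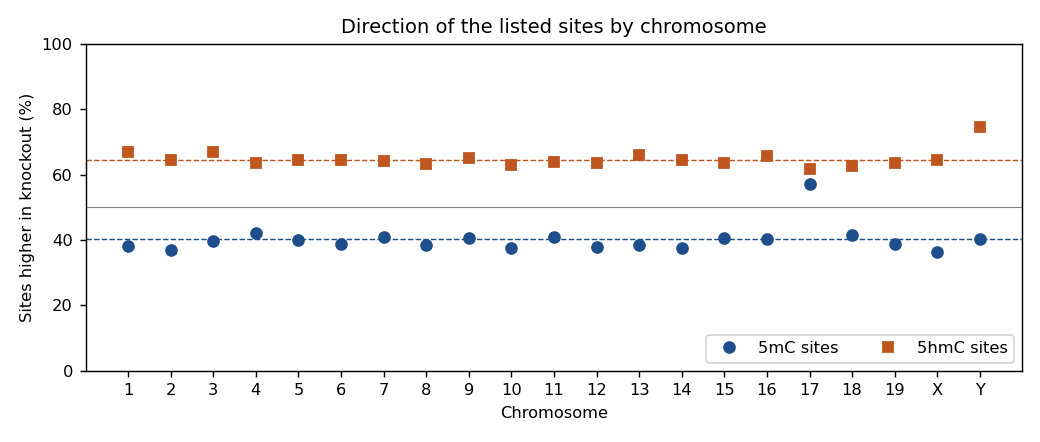
Share of listed sites higher in the knockout (percent, vertical axis) by chromosome (horizontal axis) for 5mC (circles) and 5hmC (squares); dashed lines mark the share over all sites of each table and the grey line marks 50%. For 5mC, the autosomes other than 17 lie between 36.9 and 42.2% and chromosome 17 lies at 57.1%; 5hmC lies between 62.8 and 66.9% on the autosomes other than 17.

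Direction was similar across the autosomes except chromosome 17. There 57.1% of 2871 5mC sites were higher in the knockout, against 36.9 to 42.2% on the other autosomes. From 24 to 52 Mb of that chromosome, which includes the major histocompatibility complex, 1107 of 1578 sites (70.2%) were higher, and on the rest of the chromosome 41.2% of 1293 sites were higher. Runx2, Ccnd3, Hspa1a and Hspa1b lie in this stretch. Ccnd3, which encodes the G1 cyclin D3, was at 13.3% in wild type and 91.7% in the knockout (p = 6.88e-05, q = 0.978 in the authors' deposited table). Shorter stretches with a prevailing direction were chromosome 2 from 118 to 124 Mb (282 of 316 sites lower), chromosome 3 from 148 to 154 Mb (112 of 155 higher) and chromosome 7 from 82 to 86 Mb (82 of 117 higher). These stretches were picked out of all windows of the genome after their values were seen.

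Chromosome X held 1419 5mC sites (2.67% of the list) and 910 5hmC sites (1.27%). Of the X-linked 5mC sites 36.3% were higher in the knockout, against 40.4% on the autosomes, and of the X-linked 5hmC sites 64.4% were higher, against 64.3% on the autosomes. On X beyond 4 Mb of Hdac6, 39.95% of 1199 5mC sites were higher, so the lower share of X came from the sites near Hdac6. Within 4 Mb of Hdac6, 184 of 220 5mC sites were lower. At 93 of the 220 (42.3%) the level was at least 50% in wild type and at most 5% in the knockout, against 3.84% of sites on the rest of X and 1.63% on the autosomes. Beyond Gata1 and Wdr13, this stretch held Sytl5 and Rpgr; Bcor, a corepressor gene mutated in myeloid leukaemia, lay just outside it and was at 100% in wild type and 0% in the knockout at position 12073864 (p = 0.000333, q = 1 in the authors' deposited table). Chromosome Y held 1139 listed 5mC sites, of which 1076 had levels above 0 in both genotypes.

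**Figure D2:**
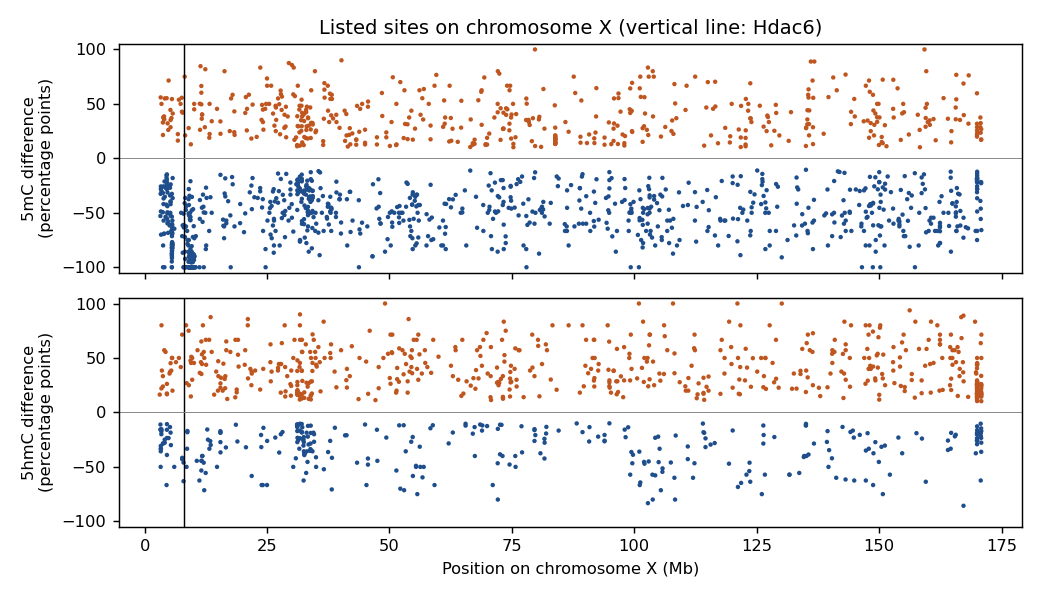
Difference in level at each listed site of chromosome X (knockout minus wild type, percentage points, vertical axis) against position (Mb, horizontal axis) for 5mC (upper panel) and 5hmC (lower panel), with higher sites in orange, lower sites in blue and Hdac6 as a vertical line. Near Hdac6, 184 of 220 5mC sites are lower in the knockout, many of them close to -100 points.

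5hmC was higher in the knockout at most listed sites, but runs of neighbouring sites were divided, with 112 higher and 115 lower. Among the named genes with the largest gains, Catspere2, Gm1604a, Vwa3b, Pelp1 and Mapk14 each had a site at 0% in wild type and 100% in the knockout of the authors' deposited table. Mapk14 encodes the stress kinase p38-alpha. Olfr1247, Tmem26, Lgals3, Zfp704 and Lsamp each had a site at 100% in wild type and 0% in the knockout, and Ezr, the gene of the membrane linker ezrin, had a site at 90% and 0%. The smallest q among these genes was 0.228 in the authors' deposited table, at Catspere2 and Olfr1247.

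Of the 71864 5hmC sites, 46265 were higher and 25599 lower, a share of 64.4% higher (95% interval 64.0 to 64.7%). The median difference was 22.22 points over all listed sites, 31.25 at the higher and -26.2 at the lower sites. Wild type was at exactly 0 at 52.3% of sites and the knockout at 30.01%. Sites between genes were higher in 67.8% of 26770 cases, sites inside genes away from their ends in 63.5% of 31028, and sites near gene ends in 59.6% of 13720. The q in the authors' deposited table was under 0.05 at 779 sites (472 higher, 307 lower) and equal to 1 at 86.6%, from a p of about 0.00074. Of the 20 sites with the smallest q, 16 lay outside genes and their ends. At chromosome 10 position 3113005, with p and q given as 0, levels in the authors' deposited table were 0.050% in wild type and 51.98% in the knockout. Sites with q under 0.05 crowded in some windows, with 16 on chromosome 10 from 3.1 to 3.2 Mb. Chromosome 1 from 88.2 to 88.3 Mb held 26, and unplaced scaffolds held 39. Read depth there is unknown, so the smallest q need not mark the largest differences.

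Among the enzymes of the 5mC and 5hmC pathway, Idh1 and Tet2 had no listed site in either table. Idh2, the mitochondrial isocitrate dehydrogenase gene, had no 5mC site and 4 5hmC sites, all higher. Tet1 had 1 5mC site, higher in the knockout at chromosome 10 position 62870309 (50% and 96.3%, p = 0.000201, q = 1 in the authors' deposited table), where 5hmC was lower (41.7% and 0%, the authors' deposited table); of its 4 5hmC sites 2 were higher and 2 lower. Tet3 had 4 5mC sites, 2 in each direction, and 6 5hmC sites, 4 of them higher. Dnmt1, the maintenance methyltransferase gene, had 3 5mC sites, all lower, and 2 5hmC sites in opposite directions. Dnmt3a, a de novo methyltransferase gene, had 5 5mC sites (2 higher, 3 lower) and 15 5hmC sites (9 higher, 6 lower). Dnmt3b had 3 5mC sites, 2 of them higher, and 2 5hmC sites in opposite directions. Over the list of 27 DNA methylation, TET and IDH genes, 16 held a 5mC site and 14 a 5hmC site, at percentiles 72.3 and 19.5 of random lists; at gene ends alone 11 held a 5mC site (random median 6, percentile 97.8). Elsewhere in this list, Mbd2 was lower in 5mC (100% and 36.4%, q = 1 in the authors' deposited table).

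Genes of stem cell identity and self-renewal held listed sites in both tables more often than random genes of like length. For no list do the random lists allow for differences in CpG density or coverage between genes. For 5mC, 32 of 40 members held a site (random median 24, percentile 99.9), 10 with higher sites alone, 9 with lower sites alone and 13 with both. For 5hmC, 32 of 40 members held a site (random median 26, percentile 98.99), 11 with higher sites alone, 2 with lower alone and 19 with both. Runx1, a core stem cell transcription factor gene, was at 100% 5mC in wild type and 16.7% in the knockout at chromosome 16 position 92803154 in the authors' deposited table. Lmo2 was at 11.1% and 90% 5mC in the authors' deposited table. Mecom had opposite differences at a single position, chromosome 3 position 30228631, with 75% and 0% 5mC but 0% and 85.7% 5hmC in the authors' deposited table. Kit, the stem cell factor receptor gene used to sort these cells, had a 5hmC site at 0% and 71.4%, and Flt3 had one at 6.67% and 80%. All these sites had q of at least 0.617 in the authors' deposited table.

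Lineage genes lay below the 95th percentile of random lists by members, but erythroid and megakaryocyte genes lay above it for 5hmC at gene ends (15 of 30 members, random median 9, percentile 99.04). Counted by sites, the erythroid list lay at percentiles 97.7 for 5mC and 96.2 for 5hmC, and the myeloid list at 96.9 for 5hmC. Of 30 myeloid genes 15 held a 5mC site (percentile 94.3) and 18 a 5hmC site (percentile 94.9); Gfi1 was at 100% and 28.6% 5mC and Csf2rb at 78.6% and 15.4% in the authors' deposited table. Of 30 erythroid and megakaryocyte genes, 15 held a 5mC site and 18 a 5hmC site (percentiles 58.7 and 76.0), with Vwf at 66.7% and 0% 5mC and Ank1 at 10% and 83.3% 5hmC in the authors' deposited table. Of 32 lymphoid genes, 19 held a 5mC site and 21 a 5hmC site (percentiles 82.6 and 82.2). Gata3 was at 12.5% and 88.9% 5mC, and Pax5, the B-cell identity factor gene, was at 91.7% and 16.7% 5mC and, at another position, at 0% and 71.4% 5hmC in the authors' deposited table. No site named in this paragraph had a q under 0.05 there.

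Stromal, endothelial and bone-cell genes, a list made for other cells of marrow, held 5hmC sites more often than random genes when counted by members. The difference between both marks was not tested. Of 22 members, 18 held a 5hmC site (random median 13, percentile 98.7) and 12 a 5mC site (percentile 53.4). Counted by sites, the order turned, with percentiles 90.5 for 5hmC and 95.7 for 5mC. Runx2, the osteoblast transcription factor gene, held 18 sites in each table. Its site at chromosome 17 position 44567474 was at 65.4% 5hmC in wild type and 0% in the knockout (p = 5.82e-09, q = 8.83e-05 in the authors' deposited table). Pdgfrb was at 78.6% and 16.7% 5hmC, and Pecam1 at 0% and 53.3%, in the authors' deposited table, with q of at least 0.556 at both.

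Genes of myeloid leukaemia held listed sites less often than random genes of like length. For each mark, 15 of 30 members held a site, against random medians of 20 for 5mC (percentile 2.81) and 21 for 5hmC (percentile 0.70). At gene ends alone the percentiles were 1.46 for 5mC and 13.0 for 5hmC, and against random lists not matched on length, 79.8 and 51.6, so the deficit depended on the matching and, for 5hmC, on sites away from gene ends. Smc3, a cohesin gene, had opposite differences at chromosome 19 position 53602002, with 78.9% and 0% 5mC but 7.14% and 100% 5hmC in the authors' deposited table. Of 29 acetylation enzyme genes, 13 held a 5mC site (percentile 4.51) and 19 a 5hmC site (percentile 53.1); Hdac4 was at 100% and 16.7% 5mC and Sirt3 at 0% and 66.7% 5hmC in the authors' deposited table. Of 33 cell cycle and quiescence genes, 17 held a 5mC site and 20 a 5hmC site (percentiles 42.9 and 54.0). Ccnd3 was higher in 5mC, as given above. Cdk6 was at 89.5% and 22.2% 5mC, and Rbl2 at 84.6% and 14.3% 5mC, in the authors' deposited table. Of the 50 5mC sites of this list 28 were higher (random median 42.0%), and of the 87 5hmC sites 40 (random median 61.6%). Without Cdkn1c, 58.0% of 69 5hmC sites were higher. Of 36 Wnt and Notch genes, 24 held a 5mC site and 27 a 5hmC site (percentiles 89.7 and 94.9), with Lrp5 at 0% and 83.3% 5hmC in the authors' deposited table. All sites named in this paragraph had q of at least 0.511 there. All 24 long neuronal genes, taken as a comparison for length, held sites in both tables (percentiles 87.3 and 88.0), where the random medians of 23 left little room. Counted by sites, this comparison list lay at percentile 100 for 5mC (371 sites, random median 167) and 96.1 for 5hmC (341 sites, random median 211), so matching on length does not make site counts neutral. Against random lists not matched on length, 6 lists in 5mC and 7 in 5hmC lay above the 95th percentile, in place of 2 and 3 with matching.

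**Figure D3:**
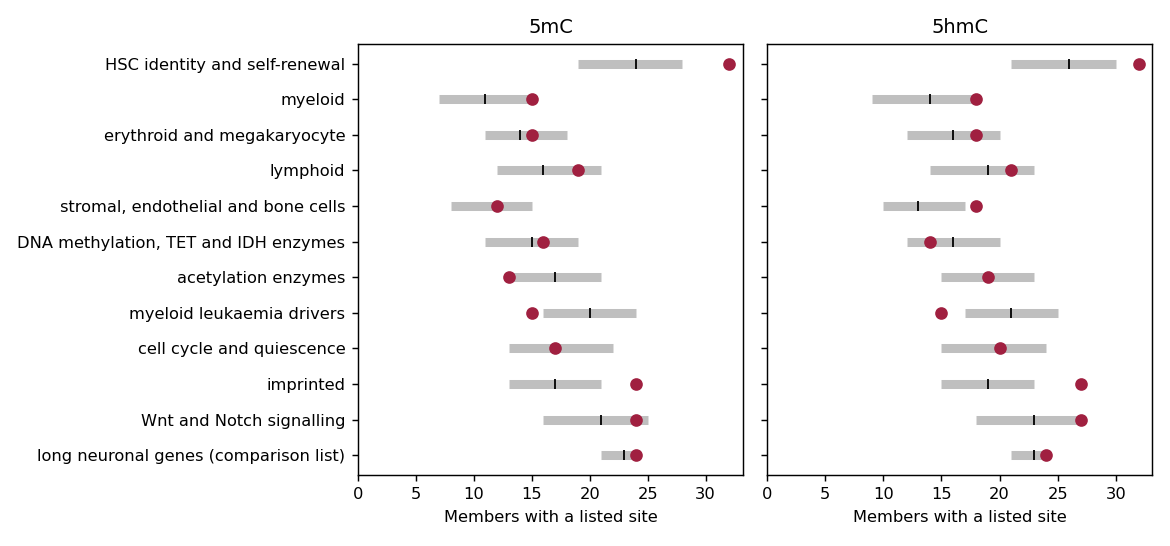
Number of members of each gene list with at least 1 listed site (red points, horizontal axis) for 5mC and 5hmC, beside 10000 random lists matched on gene length (grey bars from the 5th to the 95th percentile, black ticks at the median). Stem cell and imprinted genes lie above the bars in both panels, stromal genes in the 5hmC panel, and leukaemia genes below them in both.

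Imprinted genes also held listed sites more often than random genes. For 5mC, 24 of 33 members held a site (random median 17, percentile 99.8), and for 5hmC 27 of 33 (random median 19, percentile 99.9). In these counts a site in overlapping members, such as Kcnq1 and Kcnq1ot1, counted for each of them, which can raise the percentile. Snrpn was at 0% and 87.5% 5mC, and Plagl1 at 0% and 70% 5mC, in the authors' deposited table, with neither q under 0.05. Counted by sites, 64 of 100 5mC sites in imprinted genes were higher in the knockout, against a random median of 41.3%, and 100 of 215 5hmC sites were higher, against 62.8%. Kcnq1, the potassium channel gene that contains the imprinted antisense RNA gene Kcnq1ot1, gave 26 of these 5mC and 45 of these 5hmC sites; without it 56.8% of 74 5mC sites and 52.9% of 170 5hmC sites were higher.

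A run of neighbouring sites inside Kcnq1 and Kcnq1ot1 differed in both marks. Which libraries gave each level is not stated, so both marks are not counted as independent differences here. From position 143295628 to 143295770 of chromosome 7, 15 sites averaged 38.2% 5mC in wild type and 66.2% in the knockout. From 143295570 to 143296408, 27 sites averaged 21.5% 5hmC in wild type and 0.103% in the knockout. In the same imprinted domain, Cdkn1c, which encodes the cell cycle inhibitor p57, held a run of 12 sites at 19.8% and 0.711% 5hmC. Gnas held a run of 9 sites at 34.2% and 65.2% 5mC. Runs of 5hmC sites were lower in the knockout at H19, Dlk1 and Mest and higher at Igf2r with Airn, at Nap1l5 and at Snrpn. The smallest q within the Kcnq1ot1 runs was 0.371 for 5mC and 0.00375 for 5hmC in the authors' deposited table. At the other runs named here the smallest q in the authors' deposited table was 0.744 at Cdkn1c, 0.176 at Igf2r with Airn, 0.380 at Snrpn, and 1 at Gnas, H19, Dlk1, Mest and Nap1l5.

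**Figure D4:**
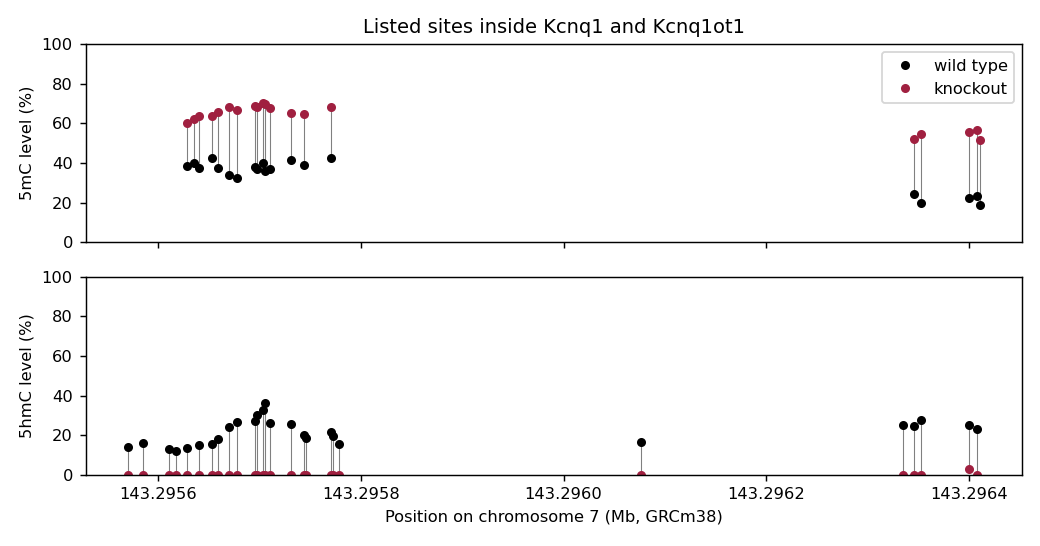
Level (percent, vertical axis) of 5mC (upper panel) and 5hmC (lower panel) at each listed site of the Kcnq1ot1 runs against position on chromosome 7 (Mb, horizontal axis), in wild type (black) and knockout (red), with a grey line joining both levels of a site. Across the first run the means are 38.2% and 66.2% for 5mC, and across the 27 5hmC sites they are 21.5% and 0.103%.

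5mC and 5hmC differed in opposite directions at nearly all positions listed in both tables. Of 12608 shared positions, 9015 were lower in 5mC and higher in 5hmC, 3579 were the reverse, and 14 differed in the same direction. At Fzd4, a Wnt receptor gene, position 89408456 of chromosome 7 was at 14.3% and 100% 5mC but 83.3% and 0% 5hmC in the authors' deposited table. The same position was listed in both tables at the gene ends of Olfr1247, Abcd2, Gulp1, Ncoa7, Olfr806, Ube2r2 and Tspan8, and at Stxbp5l different positions were listed. Abcd2 was at 81.8% and 0% 5mC, and at 0% and 100% 5hmC, in the authors' deposited table. Neither Fzd4 nor Abcd2 had a q under 0.05 at these sites. Shared positions made up 23.7% of the 5mC list and 17.5% of the 5hmC list, and drawing both lists at random from the tested cytosines would give about 227. The median sum of both levels at shared positions was 93.3% in wild type and 92.5% in the knockout, and the median change of the sum was 0 points. Which libraries gave each level is not stated; if 5hmC was obtained by subtraction, both marks at a position are not independent.

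By gene, 10313 protein-coding genes held a 5mC site, 11754 held a 5hmC site and 8070 held both, against 6506 on average (6390 to 6635) in 10000 draws matched on gene length. At gene ends 2809 genes held both, against 1602 on average. Part of this excess came from positions listed in both tables; without them 6310 genes held both, against 5319 on average (5186 to 5449), and at gene ends 1730, against 1165. The draws do not allow for differences in CpG density or coverage between genes.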

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

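The q-value, stretch, other-table, run, site-count and shared-position alternatives were chosen after the result was seen; the others were planned. Of the alternative values, 15 stayed within their limits, 26 moved and 3 turned direction. The share of sites higher in the knockout turned for 5mC to 55.6% at q under 0.05 outside the Hdac6 and chromosome 17 stretches and to 62.2% over runs of neighbouring sites, and for 5hmC to 49.3% over runs; at q under 0.05 outside the stretches it was 61.2% for 5hmC. The share of 5mC sites higher in the knockout was 39.6% at a difference of at least 15 points, 40.9% for sites with p-values below the median, 36.6% at q under 0.05, 39.5% without the Hdac6 and chromosome 17 stretches, 44.0% at sites absent from the 5hmC table and 45.0% with coding genes counted once per direction. The same settings, the stretches aside, gave 65.2, 63.9, 60.6, 62.8 and 57.4% for 5hmC. Median differences were -25.0 points for 5mC with either the larger difference or the smaller p-values, and 23.8 and 24 points for 5hmC. Gene ends alone left 2809 genes with both marks, and ends of 1000 bp held 8.88% of 5mC and 11.3% of 5hmC sites. With random lists not matched on length, 6 lists in 5mC and 7 in 5hmC exceeded the 95th percentile, in place of 2 and 3. Counting sites gave 5 and 6. Counting sites without each list's top gene gave 1 for 5mC, the long neuronal comparison list, and 2 for 5hmC; the stem cell list (87.8) and the imprinted list (91.8) then fell below the 95th percentile for 5mC, as did the stromal list (from 95.7 to 59.8), which by sites was already below it for 5hmC. Those random lists kept their own top genes; with these removed too, 5 and 6 lists exceeded it, with the stem cell list at 98.9 and the imprinted list at 99.75 for 5mC, and the stromal list at 93.0 for 5mC and 93.6 for 5hmC. The narrower sets hold fewer sites by construction; the cause of the other shifts was not tested. No paired analysis was possible because each group has 1 library. Minimums on CpGs per region and on coverage, and tests of read counts, were not run because the tables hold single positions without counts. Unknown depth limits every single level.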

Other observations

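The tests of runs of sites, of sequence variants and sex near Hdac6, and of how both marks were derived were chosen after the result was seen.

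Runs of neighbouring sites that all differed in the same direction were found at list genes and at genes outside the lists. There were 127 such runs for 5mC among 136 groups of close sites (79 higher, 48 lower) and 227 for 5hmC among 388 (112 higher, 115 lower). With directions shuffled over sites, the averages were 13.6 and 50.4 and the maxima 26 and 73. Such close sites can share reads of a single library, so a common direction needs no genotype difference, and the shuffles treat them as independent. Mpp7, a cell polarity gene, held the run with the most 5mC sites, 26 sites at 16.0% in wild type and 31.5% in the knockout. Dmd, the dystrophin gene, held 19 sites at 79.4% and 96.7%, Vkorc1l1 held 18 at 13.4% and 55.8%, and Rasa2, a Ras GTPase-activating gene, held 14 at 43.3% and 0%. For 5hmC, Dgkg held 19 sites at 0% and 28.9%, Socs3, the cytokine feedback inhibitor gene, held 8 at 22.9% and 3.07%, and Hdac7 held 7 at 0% and 23.5%.

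In 20 places a 5mC run overlapped a 5hmC run, and in all 20 the directions were opposite. Of all positions listed in both tables, 99.9% differed in opposite directions, so opposite directions in overlapping runs are no separate result. Which libraries gave each level is not stated, so both marks of a run are not counted as independent. 5mC was higher and 5hmC lower in 14 of the 20 places, the reverse of the prevailing directions of both tables. Prdm16, a stem cell transcription factor gene, had 8 sites at 66.2% and 91.2% 5mC and 9 sites at 33.2% and 3.26% 5hmC. Notch2 went the other way, with 4 sites at 69.9% and 20.998% 5mC and 4 at 3.70% and 46.1% 5hmC. Zfp423 held overlapping runs of both kinds: 76.8% and 33.5% 5mC at 7 sites, and 22.7% and 55.0% at 4 other sites.

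The 5mC sites near Hdac6 that were emptied in the knockout, from 50% or more to 5% or less, spread from 4.04 to 11.2 Mb with a median spacing of 11810.5 bp. They were not spread evenly around the gene, with 17 at positions below Hdac6 and 74 above it. From 8 to 10 Mb there were 57 of them. Conversion of 5mC to 5hmC is argued against: such sites were also higher in 5hmC 0.0324 times as often as emptied autosomal sites. A difference in sex or X number would act on the whole chromosome, but on the rest of X emptied sites were 0.0908 times as frequent. Lower sites here were at 5% or less in the knockout 9.33 times as often as lower autosomal sites, which restates the pattern. Of the 184 lower sites, 91 were at exactly 0% in the knockout, and the stretch held 1 run of neighbouring sites. Sequence variants carried along with the targeted allele, which read as unmethylated where a C is lost, could give this pattern. So could a local effect of the deletion. They cannot be told apart, since neither sequence nor strain was analysed and neighbouring cytosines that were not listed were not used here.

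The stretch of chromosome 17 with mostly higher 5mC had a median wild-type level of 29.6% at its higher sites, against 53.6% on the other autosomes, and a median knockout level of 77.8%, against 94.4%. Sequence variants on 1 of the 2 chromosome copies of the wild-type animal could lower the wild-type level, but would leave it near the middle of the scale and the knockout near full methylation; the levels lie outside that range and also differ from the other autosomes, so this cannot be told apart from other causes. Wild-type 5hmC read as 5mC in the knockout is left open as well, since higher sites here were also lower in 5hmC 0.757 times as often as on the other autosomes, short of either limit set. Of the 1777 5hmC sites of the stretch 57.9% were higher in the knockout, against 64.4% on the other autosomes. Higher 5mC sites of chromosome 3 from 148 to 154 Mb had medians of 25.7% in wild type and 75% in the knockout. Those of chromosome 7 from 82 to 86 Mb had medians of 30.3% and 82.3%. Lower sites of chromosome 2 from 118 to 124 Mb had medians of 100% and 65.4%. Levels like those of the chromosome 17 stretch are thus not particular to it. A response of the chromosome 17 stretch to the loss of HDAC6 stays open and was not tested with other animals.

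At shared positions both marks mirrored each other: 99.9% differed in opposite directions, and both levels added to at most 100% at 97.2% of positions in wild type and 94.1% in the knockout. That could follow from a 5hmC level derived with the 5mC measurement of the same site. Error in that 5mC measurement would then also move both marks in opposite directions. A 5mC level that includes 5hmC, as plain bisulfite sequencing gives, would not lie below 5hmC, yet 5hmC exceeded 5mC at 29.3% of shared positions in the knockout and 8.91% in wild type. Conversion of 5mC to 5hmC in the knockout stays open for the 9015 positions with 5mC lower and 5hmC higher, but would not give the 3579 positions with the reverse.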
